A study of Homo sapiens with 4 samples.

How the data were processed

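RNA from 2 RWPE lines was compared with RNA from 1 control line on 4 microarrays. RWPE is an established, immortalised benign prostate epithelial cell line. Each SChLAP1 line stably carried 1 isoform of the long noncoding RNA SChLAP1 on a lentiviral vector with blasticidin selection, and the control line carried LACZ on the same kind of vector, per the labels' protocols. Every array held RNA of a SChLAP1 line in Cy5 and LACZ RNA in Cy3, per the labels, and the dyes were not swapped. There were 2 arrays of each isoform line, which the labels call technical replicates, so the arrays of a line were counted as 1 replicate. Replicate 1 of both isoforms lay on slide 1 and replicate 2 of both on slide 2, and each slide was a scan batch of its own, per the file headers.

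The deposited scanner files give the intensity of each spot in both channels with its local background, per the file headers. Their deposited log10 ratios are Cy5 over Cy3 of signals that the scanner software had background-subtracted, detrended and dye-normalized by linear and lowess steps, per the file headers. The deposited value table holds log2 ratios. Each of its columns equalled the log10 ratio of the same array times 3.32, in the same direction, for 100% of 43529 features within 1e-06. Its scale, centring and direction are therefore known. The median of each column was 0, and between 16.4% and 20.1% of values were exactly 0. The other deposited columns used here are flags for spots well above background, saturated spots, outlier spots and control spots, set by the scanner software per the file headers. The software was Agilent Feature Extraction, version 8.5.1.1 per the submitters' processing notes and version 9.5.1.1 per the file headers. Probe coordinates are on hg18, per the file headers.

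Each array had 45015 spots, of which 43376 were not controls, for 41000 probes. Of the non-control spots, 63.0% to 68.9% were well above background in Cy5 and 59.3% to 64.9% in Cy3, and between 4 and 23 spots per array were outliers. At most 13 spots were saturated in Cy5 and 1 in Cy3. The number of lines and of arrays limits the precision.

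The mean signals were corrected with normexp on the median local background (offset 50), and the log2 ratios were normalized by loess within each array with control spots at weight 0. Outlier spots were left out and the spots of a probe were averaged. Probes were kept if well above background in Cy5 on both arrays of at least 1 line or in Cy3 on all 4 arrays. The brightest probe by mean signal stood for a gene, which left 19975 genes, 13438 of them with a current symbol. Symbols came from accessions and older names in the files matched to a RefSeq gene table of another genome build, used for names only. A symbol was found for 27777 of 41000 probes (67.7%), and the others kept the name in the files.

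For the comparison with LACZ, the 2 arrays of each line were averaged, and limma (version 3.58.1, in R 4.3.3) tested the mean of the 2 line values against 0 with lmFit and eBayes, 2-sided, at a Benjamini-Hochberg adjusted p of 0.05. This leaves out the spread of the control line, and any gene-specific dye effect stays in the ratio. The empirical Bayes step gave every gene the same SD of 0.31 and the same SE of 0.22, so the test acted as a limit on size: the smallest ratio called was 0.55 on the log2 scale. Adjusted p-values much below the threshold follow from that common SE and do not measure the spread of the gene itself, so the SD over the 2 lines is given beside each mean.

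Within a line there were only technical replicates, so genes of each isoform against LACZ were counted by size with no test, as those at least 2-fold apart on both arrays. The isoforms were compared within slides, where the LACZ channel and dye effects cancel, and counted if at least 2-fold apart in the same direction on both slides, again with no test. The gene lists and the rule for named genes were fixed before the data were examined. The 29 lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, and again with an estimated correlation, which rests on the difference between the 2 lines alone, and with fry. Between isoforms, each list's median difference was placed among 10000 random lists of the same size matched on mean signal. Correlations between the lines were set beside 100 simulations of unchanged lines that share 1 control. The control was given the same spread as each line, which was assumed and not measured.

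Named genes follow a rule. For LACZ these are the 12 largest mean ratios in each direction among genes with a symbol that passed the threshold with the same sign on all 4 arrays. Between isoforms they are the 8 genes in each direction with the largest difference, ranked by the smaller of the 2 slides. From each list the rule takes up to 4 members, those furthest from 0 among members past the threshold. The report gives all but 1 of these for the lists past the threshold, and for most of the other lists only part of them. The genes around SCHLAP1 were always named. Of the 24 genes the first part of the rule takes, 2 are not reported here. A gene for which all probes missed the background limit on every array of a group has only a bound there. It is given as "at least N-fold", from channel values after loess and quantile normalization of the mean signals, against the higher of its own signal and the lowest signal among probes well above background. Such bounds stay open to dye bias.

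The replicate number marks a shared slide, as the labels' descriptions show. The deviations of same-slide arrays from their line's mean correlated at r = 0.11 across genes, and fits with the replicate number as a block were made. The other alternatives were the scanner software's processed signals, no background correction, a normexp offset of 16, median centring, scaling between arrays, no filter or a stricter filter, outlier spots kept, the mean of a gene's probes, the deposited value table, the 4 arrays as separate samples, the line as a random block, a mean-variance trend, a test against a 1.2-fold change, a 1.5-fold size rule, and leaving out each array. Each slide alone, random lists matched on local gene density (5 groups of genes) as well as signal, and a spike-in scaling were added after the data were seen. The spike-in scaling subtracted from each array its mean over 10 spike-in probes. That mean was taken from the scanner software's normalized ratios and subtracted from the loess ratios. The spike-in mean on the loess scale therefore need not be 0 under it.

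The procedure was tested on simulated data for the comparison with LACZ, over 19975 genes with 200 changed. Line noise was drawn from the observed differences between the isoform lines. Of genes changed by 1 on the log2 scale 78.6% were recovered, and of those changed by 2, 100%. Unchanged genes made up 21.7% of the calls, above the nominal share, and 9.80% with normal line noise. These shares hold for 200 changed genes and are not those of the genes called here. They also leave out any spread of the LACZ line, which both ratios share, so they are no error rate of the comparison with LACZ. With only hybridisation noise the size rule between isoforms took 26.0% of genes that truly differed by 1, 100% of those that differed by 2, and 0 unchanged genes. A difference of 1 lies at the limit of the rule, and arrays of a line differed by medians of only 0.07 and 0.09. These shares therefore follow from the rule and do not measure how well it finds isoform effects. A list of 30 genes shifted by 0.5 was recovered in 20 of 20 runs, and 0 of 560 unshifted lists were called. These list results leave out the spread of the LACZ line too. They are no error rate of the list calls made here, where members of a list may move together between the lines. Figures were drawn with matplotlib 3.10.9.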

Results

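Gene expression was measured in 2 RWPE lines that stably express SChLAP1, a long noncoding RNA described in aggressive prostate cancer, against an RWPE line that carries LACZ. The isoform 1 line and the isoform 2 line each had 2 two-colour arrays, with LACZ RNA in the Cy3 channel of all 4. Values are log2 ratios of a SChLAP1 line over LACZ. The 2 arrays of the isoform 1 line correlated at r = 0.98 across genes and those of the isoform 2 line at r = 0.96, while arrays of different lines correlated at 0.74. The labels give no separate cultures within a line, so these arrays show technical spread, and the 2 lines are the only replicates.

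SCHLAP1 itself had no probe that could be matched to it, so its overexpression was not analysed here. Of the 6 neighbours on the array, 5 were measured, all on chromosome 2 (hg18). ITGA4, an integrin subunit (probe at 182107845 to 182107904), passed the threshold at 0.85 ± 0.42 (SD, n = 2 lines; adjusted p = 0.000923 with limma). It was not well above background in LACZ or on the isoform 1 arrays, so its ratio in the isoform 1 line has no bound. In the isoform 2 line it was at least 1.47-fold higher. ITGA4 did not pass with median centring, no filter or the spike-in scaling. UBE2E3 (181636288 to 181636347) had 0.26 ± 0.12, PPP1R1C (182690377 to 182690436) -0.46 ± 0.14, CWC22 (180518417 to 180518476) -0.07 ± 0.61 and ITPRID2 (182503280 to 182503339) -0.32 ± 0.63, and none of these passed. For ITPRID2, 0 of 2 other probes had the sign of the one used. The list median was -0.07 (camera adjusted p = 0.808).

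The first question was which genes differ between cells with SChLAP1 and cells with LACZ. TSPYL5, FARP1 and PRDM13 lay furthest above LACZ in both SChLAP1 lines, and CX3CL1 and NEFL were among those furthest below it. TSPYL5, a nucleosome assembly family gene (chromosome 8, 98354961 to 98355020), was highest at 5.59 ± 0.10 (SD, n = 2 lines), with LACZ well above background on 2 of 4 arrays. It was followed by FARP1 (chromosome 13, 97898600 to 97898659), at 5.22 ± 0.49. PRDM13, a transcriptional regulator of neural development, had 4.86 ± 0.65, again with LACZ above background on 2 of 4 arrays. TNFRSF8, the CD30 receptor, had 4.51 ± 0.47. PHACTR3 had 4.48 ± 0.13 and TCF15, a helix-loop-helix factor of somites, 4.38 ± 0.15. TGFBI, a matrix protein induced by TGF-beta, had 4.13 ± 0.32, the linker histone gene H1-1 3.98 ± 0.45, and SGCE, a sarcoglycan, 3.72 ± 0.25. The peptide receptor gene QRFPR was not well above background in LACZ and was at least 11.8-fold higher. SPARC, a matrix glycoprotein, had 3.49 ± 0.13, with LACZ above background on 1 of 4 arrays, and was at least 10.5-fold higher in the isoform 2 line. SERPINB2, the plasminogen activator inhibitor 2, averaged 3.77 ± 2.91 because the lines lay far apart, at 5.82 and 1.71, and did not pass with median centring or no filter. The other kept probe of FARP1 gave 1.40 and that of TCF15 0.56, the same sign at a smaller size.

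The gene furthest below LACZ was CX3CL1, the chemokine fractalkine (chromosome 16, 55976366 to 55976425), at -5.09 ± 0.31 (SD, n = 2 lines). Its 2 other probes averaged -1.17. KCNMA1, a potassium channel, was -4.11 in the isoform 2 line. Its probe was not well above background in the isoform 1 line, and its 2 other probes averaged -1.11. NEFL, a neurofilament gene, had -4.15 ± 0.32. LTB, the cytokine lymphotoxin beta, had -3.99 ± 1.49, with -2.93 in the isoform 1 line and -5.04 in the isoform 2 line. KLK5, a kallikrein protease of squamous epithelium, had -3.86 ± 0.04 and CDH11, a mesenchymal cadherin, -3.68 ± 0.01, above background on 1 of 2 isoform 1 arrays. ZG16B had -3.42 ± 0.49, IL1R2, the decoy receptor for interleukin 1, -3.32 ± 0.41, and the growth factor gene IGF2 -3.20 ± 0.04. ECM2, a matrix protein gene, was -3.50 in the isoform 2 line, and in the isoform 1 line, where it was not well above background, it was at least 12.3-fold lower than LACZ.

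**Figure D1:**
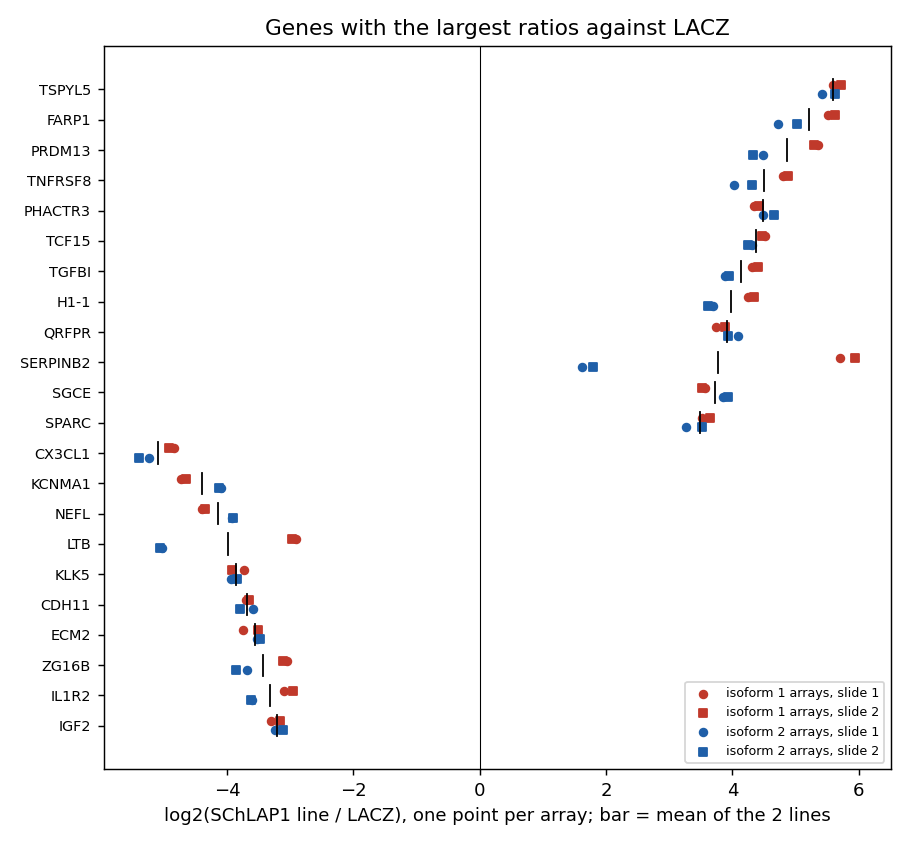
Log2 ratio of a SChLAP1 line over LACZ (horizontal axis) for the genes with the largest ratios, 1 point per array, red for isoform 1, blue for isoform 2, circles for slide 1 and squares for slide 2; black bars are means of the 2 lines. The arrays of a line lie close together, and SERPINB2 (5.82 against 1.71) and LTB (-2.93 against -5.04) are far apart between lines. QRFPR in LACZ and ECM2 in the isoform 1 line were not well above background. Nor was the KCNMA1 probe shown in the isoform 1 line.

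In all, 5055 of 19975 genes passed the threshold in limma, 2281 higher and 2774 lower in the SChLAP1 lines, and 98.9% of them had the same sign on all 4 arrays. On slide 1 alone 4931 passed, and on slide 2 alone 4763. The test gave every gene the same SE, and the count was 523 with median centring, 2259 with no filter on dim probes, 2361 against a 1.2-fold change, 442 with the spike-in scaling and 9772 with the 4 arrays as separate samples. With 1 LACZ line and no dye swap, the spread of the control and gene-specific dye effects are not covered. By size alone, 320 genes were at least 2-fold higher and 548 at least 2-fold lower on all 4 arrays.

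Among the lists fixed beforehand, 11 of 29 passed with camera at the preset correlation, 4 toward higher and 7 toward lower ratios. With an estimated correlation 0 lists passed, with 0 at an unadjusted p under 0.05, and with fry 0 passed, with 5 at an unadjusted p under 0.05. With 2 line values the estimated setting could hardly pass any list. Basal markers had an estimated correlation of -0.04, below the preset 0.01, but their unadjusted camera p of 0.09 was the lowest under it. These failures therefore do not show that correlation between genes accounts for the calls, and they do not exclude it. The estimated correlation was 0.72 for NF-kB and cytokine genes, 1 for metallothioneins, 0.30 for squamous genes and 0.11 for extracellular proteases. For the other lists that passed it lay between -0.04 and 0.05. For the former lists the preset 0.01 may be too low. With the slide as a block over 4 arrays, 7 lists passed. The calls below are relative to all genes measured. With median centring the median of all genes was 0.10, with -0.004 in the isoform 1 line and 0.23 in the isoform 2 line. In the main setting the median of all genes was 0.01, and -0.26 with the spike-in scaling, which shifts every gene of an array by the same amount and so keeps the order of the lists. Under it the median of the HOX genes was -0.05, those of cell cycle genes and histones in the isoform 1 line were -0.52 and -0.18, and 53 of the 122 genes taken by the naming rule lost their call.

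Basal epithelial markers lay below LACZ in both lines, with a median of -0.998 over 22 measured genes. Of these 16 fell, 1 rose and 5 did not pass (17 fell and 2 rose adjusted over the list alone; camera adjusted p = 2.5e-09, and adjusted p = 0.809 with an estimated correlation). Those that fell included LAMB3, a laminin chain, at -2.19 ± 0.94 (SD, n = 2 lines), the Notch ligand JAG1 at -2.15 ± 0.23, the keratin KRT14 at -1.82 ± 0.22, and TP63, the basal master regulator, at -1.78 ± 0.17. LAMB3, KRT14 and TP63 did not pass with median centring, nor did LAMA3 below, and the list median was -0.498 under it. The other probe of TP63 gave -0.502. The wider list of epithelial junction and adhesion genes did not pass (camera adjusted p = 0.07), and 9 of its 33 measured genes fell, among them CLDN1 at -1.45 ± 0.22 and LAMA3, a laminin chain, at -1.27 ± 0.02 (other probes -0.47), while 1 rose (1 and 9 adjusted over the list alone). Squamous differentiation genes passed as lower (camera adjusted p = 0.0186), but with 5 rising and 9 falling of 28 (6 and 9 adjusted over the list alone), a median of -0.08 and a mean of -0.35. The adjusted p was 0.341 with the slide as a block, 0.809 with an estimated correlation, 0.128 with median centring, 0.175 with no background correction, 0.09 with no filter, 0.0798 with scaling between arrays and 0.0512 with the processed signals, and the median was 0.00541 with median centring (adjusted p from 0.00805 to 0.809 over the alternatives). KLK8 fell to -1.94 ± 0.63 and S100A8, a calprotectin subunit, to -2.78 ± 1.91, whereas the transglutaminase TGM1 rose to 2.37 ± 0.62. S100A8 and KLK8 did not pass with median centring, nor S100A8 with no filter.

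Extracellular proteases and their inhibitors had a median of -0.62 over 32 genes, with 17 falling and 3 rising (18 and 3 adjusted over the list alone; camera adjusted p = 3.38e-05, and adjusted p = 0.809 with an estimated correlation). MMP1, interstitial collagenase, had -3.07 ± 0.22 and MMP9, a gelatinase, -2.59 ± 1.74 (not past the threshold with median centring or no filter). MMP3, stromelysin, was not well above background in either SChLAP1 line and was at least 8.48-fold lower. SERPINB2 was the highest of the members that rose.

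Targets of ATF4 and the unfolded protein response, which serve amino acid supply and protein folding under stress, had a median of -0.65 over 44 genes. Of these 24 fell and 1 rose (25 and 1 adjusted over the list alone; camera adjusted p = 3.85e-11, and adjusted p = 0.809 with an estimated correlation). ASNS, asparagine synthetase, fell to -2.83 ± 0.61, though its other probe had the opposite sign. NUPR1 fell to -2.31 ± 0.12, the serine synthesis enzyme PSAT1 to -2.22 ± 0.52 and the pseudokinase TRIB3 to -2.18 ± 0.30. ASNS, PSAT1 and TRIB3 did not pass with median centring, under which the list median was -0.31. In the isoform 2 line it was then -0.05, where that of all genes was 0.23. Cholesterol and fatty acid synthesis genes had a median of -0.47 over 35, with 13 falling and 1 rising (17 and 2 adjusted over the list alone; camera adjusted p = 0.00884, 0.0765 with median centring and 0.0512 with the processed signals, and adjusted p = 0.809 with an estimated correlation; lowest 5.94e-05 over the alternatives). HMGCS1 was at -1.24 ± 0.23, CYP51A1 at -1.20 ± 0.12 and MVD at -1.28 ± 0.49, all 3 enzymes of the sterol pathway, and the desaturase FADS2 was at 2.22 ± 0.38, with its other probe at 0.26. With median centring the list median was -0.16, and 0.01 in the isoform 2 line, again against 0.23 for all genes in that line.

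Cell cycle and proliferation genes had a median of 0.42 over 62 genes, with 23 rising and 5 falling (25 and 6 adjusted over the list alone; camera adjusted p = 0.000358, and adjusted p = 0.809 with an estimated correlation). CKS2 was at 1.21 ± 0.19, the mitotic kinesin KIF20A at 1.11 ± 0.03, TPX2 at 1.09 ± 0.05 and cyclin A2 (CCNA2) at 1.06 ± 0.07. Replication-dependent histones had a median of 0.60 over 21 genes, with 13 rising and 2 falling (14 and 2 adjusted over the list alone; camera adjusted p = 0.000609, and adjusted p = 0.809 with an estimated correlation). H4C3 was at 1.90 ± 0.21, H2BC5 at 1.75 ± 0.48 (other probe 0.26) and H4C5 at 1.23 ± 0.32. Targets of p53 had a median of -0.49 over 30 genes, with 14 falling and 2 rising (15 and 2 adjusted over the list alone; camera adjusted p = 0.01, and adjusted p = 0.809 with an estimated correlation). DDB2 at -1.12 ± 0.10 and XPC at -0.96 ± 0.09, both DNA repair genes, lay with BTG2 at -1.002 ± 0.16 and PLK3 at -0.95 ± 0.26. With median centring the median of the p53 list was -0.27, and 0.10 in the isoform 2 line, where that of all genes was 0.23. With median centring, the 4 cell cycle genes and 4 p53 targets named and H4C5 did not pass, nor did HMGCS1, CYP51A1 and MVD.

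Genes of NF-kB and cytokine signalling had a median of -0.43 over 41 genes, with 19 falling and 8 rising (20 and 9 adjusted over the list alone; camera adjusted p = 0.000563, 0.0703 with the slide as a block, and adjusted p = 0.809 with an estimated correlation; lowest 0.000435 over the alternatives). BIRC3, an inhibitor of apoptosis, fell to -2.09 ± 0.05, with LTB as above, while the chemokine CCL20 rose to 2.10 ± 0.78. The superoxide dismutase SOD2 fell to -2.08 ± 0.68 (other probe -0.60, and not past the threshold with median centring). The medians of the lines were -0.07 in isoform 1 and -0.66 in isoform 2. Metallothioneins had a median of 0.61 over 13 genes, with 9 rising and 2 falling (10 and 2 adjusted over the list alone; camera adjusted p = 0.0165, 0.157 with the slide as a block, 0.238 with the processed signals, 0.0583 with no filter, and adjusted p = 0.809 with an estimated correlation; lowest 0.00112 over the alternatives). MT1M was at 1.74 ± 1.04, the metal-responsive factor MTF1 at 0.78 ± 0.05 and MT1F at -1.64 ± 0.11. MT2A was at 0.87, with its probe saturated in Cy5 on 2 of 4 arrays, 1 isoform 2 array used and 2 other probes at 0.52 on average. With median centring the list median was 1.36, against 0.10 for all genes. MT1M and MTF1 did not pass with median centring, MT1M and MT2A with no filter, MT2A with the processed signals or MTF1 against a 1.2-fold change. HOX genes had a median of 0.23 over 27, with 6 rising and 2 falling (6 and 2 adjusted over the list alone; camera adjusted p = 0.0172, 0.157 with the slide as a block, 0.22 with the stricter filter, 0.172 with median centring, 0.0986 with no filter, 0.0681 with no background correction, 0.0532 with the mean of probes, and adjusted p = 0.809 with an estimated correlation; lowest 0.0025 over the alternatives). HOXB13, a prostate homeobox gene, was at 1.67 ± 0.15. LACZ was not well above background for HOXA13, at least 4.43-fold higher (measured ratio of its other probe 0.40), for HOXD1, at least 3.07-fold higher, or for HOXD13, at least 2.82-fold higher.

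**Figure D2:**
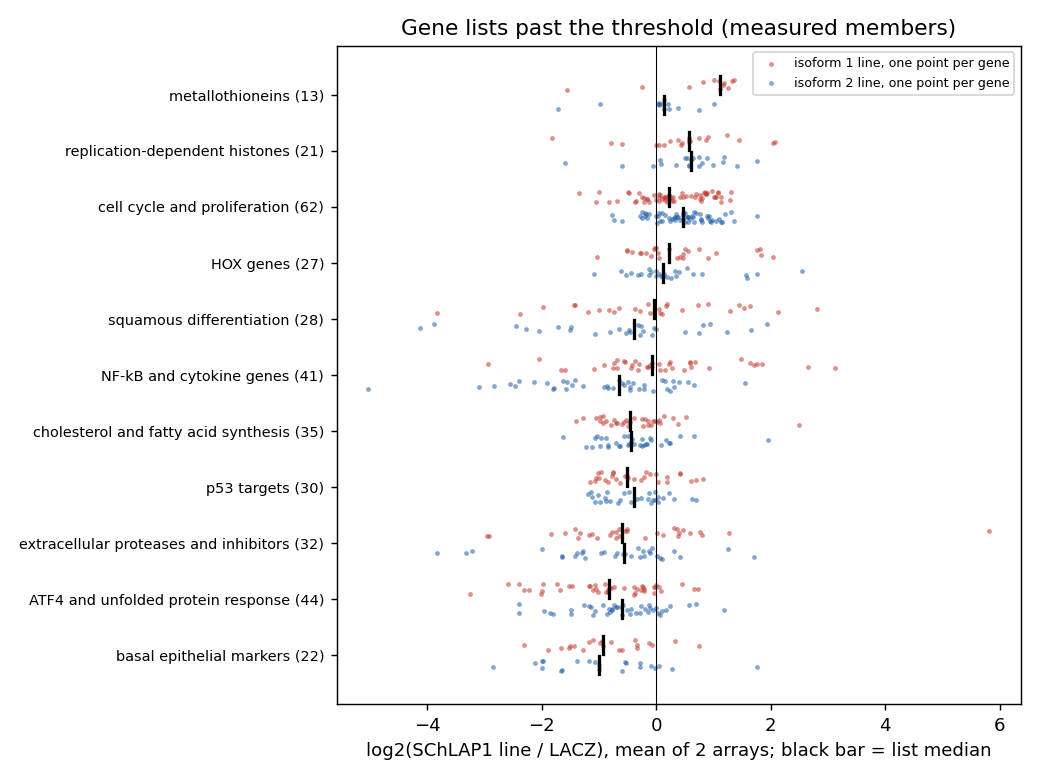
Log2 ratio over LACZ of each measured member of the 11 lists past the threshold (horizontal axis), with the number of members in parentheses, red for the isoform 1 line and blue for the isoform 2 line, 1 point per gene at the mean of 2 arrays; black bars are list medians. Basal markers have a median of -0.998, and metallothioneins have medians of 1.12 in isoform 1 and 0.13 in isoform 2.

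The other 18 lists did not pass. Of 30 measured SWI/SNF subunits, the remodelling complex, 3 rose and 5 fell (4 and 6 adjusted over the list alone; median -0.13, camera adjusted p = 0.387). DPF3 was -1.90 in the isoform 2 line, with its probe not well above background in the isoform 1 line and its other probe at -0.49, and it did not pass with the stricter filter. SMARCD3 fell to -1.65 ± 0.28 and the core subunit SMARCB1 to -0.81 ± 0.23, and ARID1A rose to 1.01 ± 0.03 with 1 of 2 other probes of that sign. SMARCB1 and ARID1A did not pass with median centring, SMARCB1 with no filter or against a 1.2-fold change, or ARID1A with the mean of its probes. Of 23 Polycomb and other chromatin genes, 1 rose and 6 fell, the former DNMT3B at 0.71 ± 0.09 and the latter including CBX7 at -0.90 ± 0.03 (1 and 6 adjusted over the list alone). Mesenchymal genes went both ways, with 7 rising and 7 falling of 27 (8 and 7 adjusted over the list alone): TWIST1 was at 2.37 ± 0.09 (other probe 0.98) beside SPARC, and TNC at -2.26 ± 0.12 beside CDH11. TGF-beta response genes had 5 rising, TGFBI highest, and 10 falling of 27 (7 and 10 adjusted over the list alone), with CDKN2B at -2.40 ± 0.70 (other probe -1.07). Among 20 luminal and androgen response genes 5 rose and 4 fell (5 and 5 adjusted over the list alone), with the luminal keratin KRT18 at 1.54 ± 0.36 and NDRG1 at -1.87 ± 0.25. Of 58 interferon response genes 12 rose and 8 fell (13 and 9 adjusted over the list alone), with tetherin (BST2) at 3.03 ± 0.21 and CXCL11 at -2.77 ± 0.31. CDKN2B did not pass with median centring, nor did CBX7 and DNMT3B, and DNMT3B did not pass against a 1.2-fold change.

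Heat shock and immediate early genes had 12 rising and 5 falling of 35 (13 and 7 adjusted over the list alone), with HSPA8 at 1.65 ± 0.24 and IER2 at -2.73 ± 0.06, its LACZ channel saturated on 2 of 4 arrays. Hypoxia and glycolysis genes had 7 and 9 of 40 (8 and 9 adjusted over the list alone), with CA12 at -1.80 ± 0.12. NRF2 targets had 2 and 5 of 29 (2 and 5 adjusted over the list alone), with AKR1C1 at -1.43 ± 0.48 and TXNRD1 at 0.82 ± 0.39, and Wnt and Notch targets 5 and 8 of 29 (7 and 10 adjusted over the list alone; adjusted p = 0.0239 with the stricter filter, up to 0.809), with DKK3 at -2.27 ± 0.18. LEF1 of that list was dim in LACZ and at least 3.42-fold higher. Cytosolic ribosomal proteins had 11 and 5 of 75 (11 and 5 adjusted over the list alone), with RPS21 at 1.18 ± 0.08 from a probe saturated in Cy5 on 2 of 4 arrays and RPL29 at -0.76 ± 0.01. Respiratory chain genes had 3 and 4 of 53 (1 and 2 adjusted over the list alone). ATP5MC3 was at 0.90 ± 0.18 (other probe 0.27), NDUFA6 at -0.72 ± 0.24, UQCRC1 at -0.68 ± 0.35 and COX4I1 at -0.60 ± 0.15 with 1 of 2 other probes of that sign. Only with median centring did these ribosomal (adjusted p = 2.8e-12) and respiratory (adjusted p = 0.00043) lists pass, both as higher (up to 0.809 and 0.984 over the alternatives). Neuroendocrine markers had 1 and 1 of 7 (1 and 1 adjusted over the list alone), with UCHL1 at 2.09 ± 0.54 and PCSK1 at -1.63 ± 0.19. Markers of other cell types did not pass either. Fibroblast and smooth muscle markers had 3 and 1 of 10 (3 and 1 adjusted over the list alone; adjusted p = 0.0469 with the processed signals, up to 0.809), with FBLN1 at -1.33 ± 0.06 and MFAP5 at 0.74 ± 0.01. LACZ was not well above background for FAP, at least 1.68-fold higher, or for DCN, at least 1.67-fold higher. Leukocyte markers had 1 and 1 of 12, with LCP1 at least 5.25-fold higher and CSF1R at -0.74 ± 0.15, and endothelial markers 0 and 2 of 7 (the same counts adjusted over each list alone). These 2 were ROBO4 at -1.13 ± 0.13, above background on 1 of 2 arrays of each line (other probe -0.43), and EGFL7 at -0.64 ± 0.51. Of the genes in this paragraph, AKR1C1, TXNRD1, RPL29, NDUFA6, UQCRC1, COX4I1, PCSK1, FBLN1, MFAP5, FAP, DCN, CSF1R, ROBO4 and EGFL7 did not pass with median centring, under which COX4I1 was at 0.09. NDUFA6, UQCRC1, COX4I1 and EGFL7 also did not pass with no filter, with the processed signals or against a 1.2-fold change. Nor did TXNRD1 and FAP with no filter, RPL29 with the processed signals, RPL29, MFAP5 and CSF1R against a 1.2-fold change, COX4I1 with the mean of its probes or ROBO4 with the stricter filter. The median and mean differed in sign for the genes around SCHLAP1 (-0.07 and 0.05), Polycomb genes (0.07 and -0.09), mesenchymal genes (0.05 and -0.11), respiratory chain genes (-0.02 and 0.004) and leukocyte markers (-0.01 and 0.18), with the test following the mean.

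Taken each on its own, the isoform 1 line had 751 genes at least 2-fold above LACZ and 969 at least 2-fold below it on both arrays. The isoform 2 line had 563 and 869. No test was made here, since each line had technical replicates only. The lines shared 320 higher genes, against 21.2 for independent lists of these sizes, and 548 lower genes, against 42.2. In 5 genes the directions were opposite. In simulations of unchanged lines against 1 control of the same spread, 41.4 higher and 40.7 lower genes were shared. A control with more spread would raise these counts. With the processed signals the totals were 3048 for isoform 1 and 2719 for isoform 2, against 1720 and 1432. The isoform 2 split turned to 1598 higher and 477 lower with median centring and to 955 and 568 with the spike-in scaling, under which isoform 1 had 118 and 5570.

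Across genes, the log2 ratios of the 2 lines correlated at Pearson r = 0.75, with a Spearman correlation of 0.66. Genes are not independent replicates, and lines with no change that share a control gave r = 0.50 in simulations. That value follows from giving the control the same spread as each line. A LACZ line with more spread would alone raise the simulated values here, so they are no benchmark for an effect of SChLAP1. The covariance was 0.29 against 0.0963 simulated. The same sign was found in 72.0% of genes, against 66.7% simulated. With 1 control line, its part in the covariance could not be separated.

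**Figure D3:**
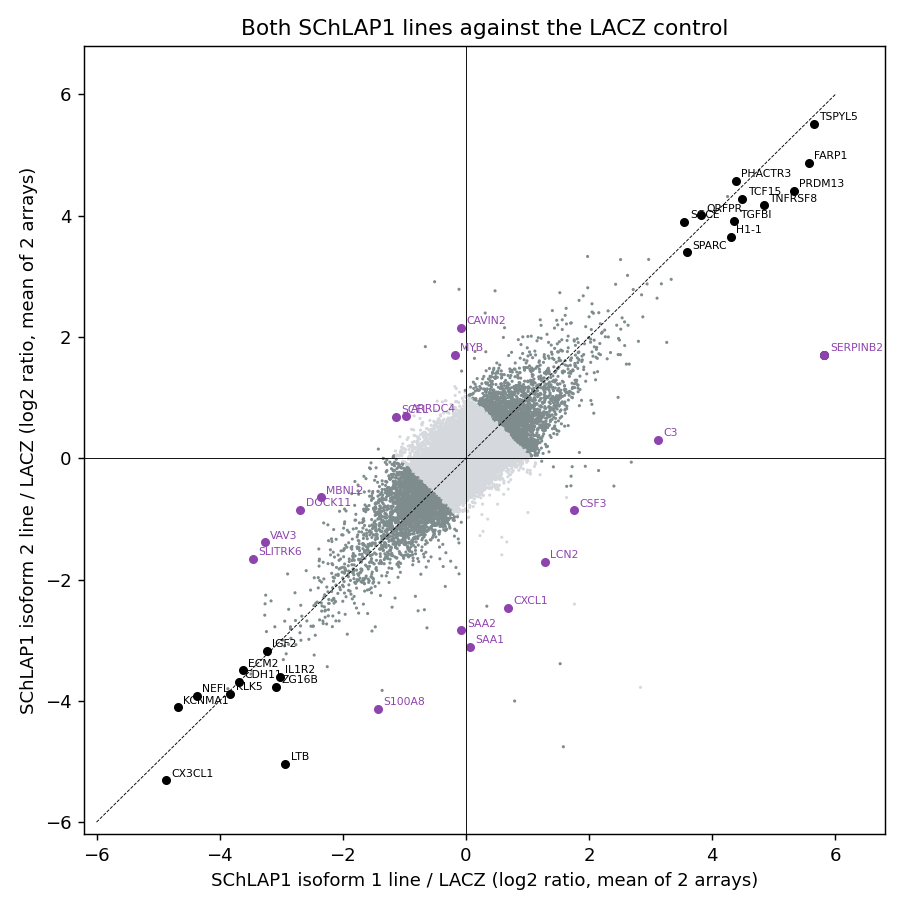
Log2 ratio over LACZ of the isoform 1 line (horizontal axis) and of the isoform 2 line (vertical axis), 1 point per gene at the mean of 2 arrays, dark grey for genes past the threshold; named genes are black and the isoform comparison's genes purple, and the dashed line marks equal ratios. Most genes far from LACZ lie near the dashed line (r = 0.75), with SERPINB2, CXCL1 and SAA1 well below it and CAVIN2 and MYB above it.

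The second question was whether the isoform lines differ from each other. SERPINB2, CXCL1 and SAA1 were furthest above isoform 2 in the isoform 1 line, and CAVIN2 furthest below. SERPINB2 (chromosome 18, 59721938 to 59721997) was highest, with a difference of 4.11 ± 0.04 on the log2 scale (SD, n = 2 slides). SAA1 and SAA2, acute-phase serum amyloid genes that are near-identical and so may share signal, differed by 3.18 ± 0.18 and 2.76 ± 0.18, though the other probe of SAA2 gave 0.36. The neutrophil chemokine gene CXCL1 differed by 3.15 ± 0.03, LCN2, an iron-binding defence protein, by 2.99 ± 0.02, complement C3 by 2.81 ± 0.12, S100A8 by 2.70 ± 0.06 and the cytokine gene CSF3 by 2.62 ± 0.16. Higher in the isoform 2 line were CAVIN2, a caveolae protein gene (chromosome 2, 192408347 to 192408406), at -2.23 ± 0.04, the transcription factor MYB at -1.89 ± 0.47, VAV3 at -1.89 ± 0.10, DOCK11 at -1.84 ± 0.19 (other probe -0.69), SCEL at -1.83 ± 0.08, SLITRK6 at -1.81 ± 0.10, the splicing regulator MBNL2 at -1.72 ± 0.21 (other probe -0.56) and ARRDC4 at -1.67 ± 0.03.

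**Figure D4:**
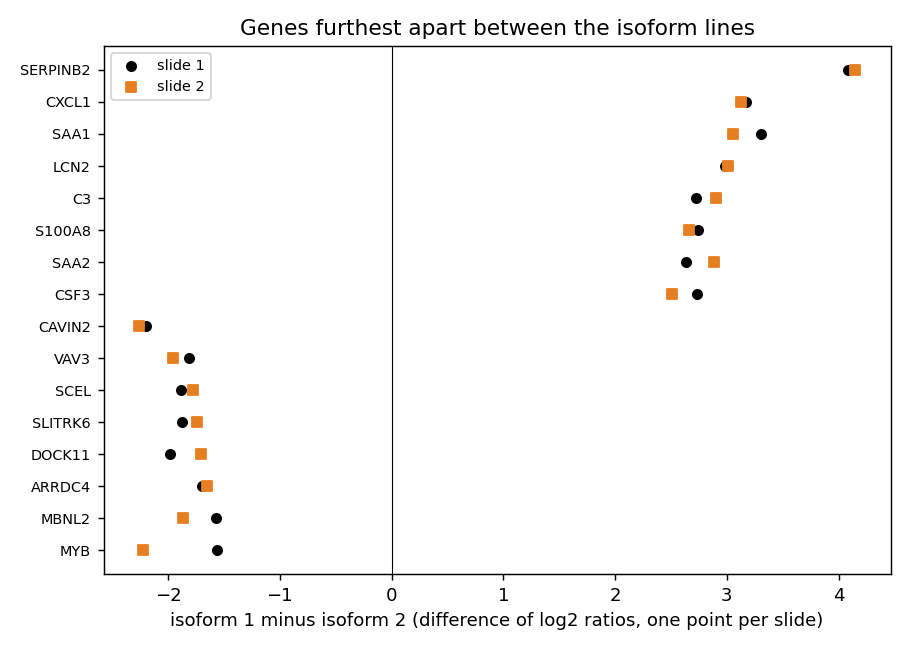
Difference between the isoform 1 and isoform 2 log2 ratios within a slide (horizontal axis) for the genes furthest apart, black circles for slide 1 and orange squares for slide 2. SERPINB2 differs by 4.08 and 4.14 on the 2 slides, and MYB by -1.56 and -2.22.

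By the size rule 93 genes were at least 2-fold higher in isoform 1 and 137 in isoform 2 on both slides, and the differences correlated at r = 0.90 between slides across genes. This compares 2 lines with no biological replicate, so it has no test of the isoforms. On slide 1 alone 378 genes differed 2-fold and on slide 2 alone 398. The split depends on the scaling: it was 53 and 1283 with median centring, 211 and 656 with the processed signals, 24 and 7233 with the spike-in scaling, and 94 and 82 with the mean of all kept probes.

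Among the lists, 11 of 29 had a median difference outside the central 95% of random lists matched on signal, 8 toward isoform 1. The difference followed local gene density across genes (Spearman correlation 0.40), and spike-in probes differed by 0.94 in the scanner software's normalized ratios. With random lists matched on density as well, 12 lists lay outside, 9 of them among the 11. Squamous genes (percentile 97.4) and leukocyte markers (96.3) no longer did. Replication-dependent histones (percentile 0.01, toward isoform 2, against 25.3 before), mesenchymal genes (99.7, against 96.1) and neuroendocrine markers (99.4, against 97.465) did so only then, with median differences of -0.05, 0.17 and 0.25. NF-kB and cytokine genes were furthest toward isoform 1 after metallothioneins, with a median difference of 0.89 and 16 of 41 genes at least 2-fold higher. Metallothioneins had a median difference of 1.01, with 5 of 13 genes at least 2-fold higher. These differences are relative to all genes. The spike-in scaling lowers the isoform difference of every gene by 0.94, slightly more than the 0.89 of NF-kB genes and less than the 1.01 of metallothioneins. The medians of the lines are another measure. With that scaling they were 0.38 in isoform 1 and 0.33 in isoform 2 for metallothioneins, and -0.82 and -0.46 for NF-kB genes. Squamous differentiation genes had 0.35, leukocyte markers 0.33, extracellular proteases 0.29, interferon response genes 0.27, NRF2 targets 0.26 and hypoxia and glycolysis genes 0.22. Toward isoform 2 were the genes around SCHLAP1 at -0.59, ATF4 and unfolded protein response genes at -0.19 and cytosolic ribosomal proteins at -0.13. SWI/SNF subunits had a difference of 0.06, at percentile 58.4 of random lists, and basal markers of 0.01, at percentile 35.9.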

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

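These results lay on opposite sides of LACZ in the isoform lines on every array, and none of the differences was tested, since there is 1 line per isoform. Differences are isoform 1 minus isoform 2 on the log2 scale. CXCL1 differed by 3.15 (0.68 in isoform 1 and -2.46 in isoform 2), SAA1 by 3.18 (0.07 and -3.11), LCN2 by 2.99 (1.28 and -1.71) and CSF3 by 2.62 (1.76 and -0.86). In the other direction CAVIN2 differed by -2.23 (-0.08 and 2.15), MYB by -1.89 (-0.19 and 1.71), SCEL by -1.83 (-1.14 and 0.69) and ARRDC4 by -1.67 (-0.98 and 0.70). Of the genes around SCHLAP1, CWC22 differed by -0.86 (-0.50 and 0.37) and ITPRID2 by -0.89 (-0.77 and 0.12), and the median of that list by -0.59. The sides depend on the scaling: with the spike-in scaling, chosen after the data were seen, both lines lay below LACZ for CXCL1 (-0.06 and -2.27) and SAA1 (-0.67 and -2.91).

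Some lists had medians on opposite sides of 0 by small amounts, which also depended on the scaling. With median centring all genes had -0.004 and 0.23 in isoform 1 and isoform 2. Mesenchymal genes then had 0.07 and 0.14, hypoxia and glycolysis genes 0.14 and 0.26, and cytosolic ribosomal proteins 0.50 and 1.13. The median difference was 0.17 for mesenchymal genes, 0.22 for hypoxia and glycolysis genes, -0.13 for cytosolic ribosomal proteins, 0.0328 for Wnt and Notch targets, 0.33 for leukocyte markers and 0.21 for endothelial markers. For respiratory chain genes the median of the differences was 0.0235, but 0.09 on slide 1 and -0.03 on slide 2, and the line medians were -0.02 and 0.02, so no direction is given.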

How the results depend on the processing

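Each slide alone, matching on gene density and the spike-in scaling were chosen after the data were seen. The count of genes against LACZ stayed within 1.5 times of 5055 in most settings. These included the replicate block (7390 genes, 4673 of them also in the main result), each slide alone and leaving out each array (4937 to 5472). A similar count did not always mean the same genes. With the processed signals 4507 genes passed, and only 3444 of them were also in the main result. For the deposited log2 ratios the overlap was 3450 of 4517 genes. It was 4712 of 5080 with a normexp offset of 16 and 5032 of 5036 with outlier spots kept. The block counts technical arrays as samples, and the slide and leave-out settings only exchange technical replicates of the same lines. They therefore show technical stability alone. Other settings changed the count more. It was 523 with median centring (282 higher and 241 lower), 2259 with no filter, 2361 against a 1.2-fold change, 442 with the spike-in scaling (69 and 373) and 9772 with the 4 arrays as separate samples. The prior degrees of freedom of the empirical Bayes step were infinite in the main setting, 3.39 with median centring and 2.90 with no filter. With a finite prior the SD of a gene over the 2 lines enters its test, which it does not in the main setting. Of the 2259 genes called with no filter 2253 were also in the main result, and of the 523 with median centring 522. The cause of the lower counts was not tested further. With the processed signals 2412 were higher and 2095 lower, against 2281 and 2774.

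Of 29 lists, 11 passed, 7 with the replicate block or with 4 separate arrays, and 0 with an estimated correlation or with fry. The estimated correlation could hardly pass any list, as said above. Leaving out each array kept 11 in every case, which again exchanges technical replicates only. With the block the adjusted p was 0.0703 for NF-kB genes, 0.157 for metallothioneins and for HOX genes, and 0.341 for squamous genes.

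The 2-fold count for isoform 1 was 1720, and 3048 with the processed signals or the deposited value table, 5688 with the spike-in scaling (118 and 5570) and 5065 at 1.5-fold. For isoform 2 it was 1432, and 2719 with the processed signals or the value table and 4165 at 1.5-fold. Leaving out an array gave 1955 to 1968 and 1651 to 1668. With median centring its split was 1598 higher and 477 lower, against 563 and 869, and with the spike-in scaling 955 and 568. With median centring the medians over genes of the isoform 2 arrays were 0.26 and 0.22, and the isoform 2 split moved in that direction. The spike-in scaling shifts a whole array by the same amount, by definition. What else changed the counts was not tested.

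Between isoforms, 230 genes were 2-fold apart, 867 with the processed signals or the value table, 1336 with median centring, 7257 with the spike-in scaling (24 and 7233) and 2454 at 1.5-fold. Leaving out an array gave 378 to 398, since only 1 slide then sets the rule. Limma over hybridisations called 11772 genes with the replicate block and 11916 without it; these cover hybridisation spread only and test no isoform effect. With the mean of a gene's probes 94 were higher in isoform 1 and 82 in isoform 2.

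The correlation between lines was 0.75, 0.72 with median centring, 0.74 with no filter and 0.75 with the mean of probes, and between 0.74 and 0.75 on leaving out an array. The count of lists apart between isoforms, 11, ranged within 1.5 times in each setting.

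Of 2659 values of 122 named genes against LACZ under 22 alternatives, 2494 kept their side of the threshold and direction, 161 lost the call, 55 of them with median centring and 53 with the spike-in scaling, 3 gained it and 1 reversed: COX4I1 was 0.0895 with median centring, against -0.60. Most of these genes were named for large ratios in these same data. The share kept is therefore not that of all genes called. Between isoforms, 105 of 160 values moved by less than the spread between slides, and 0 reversed. Dim spots limit ratios: the bounds given above hold for genes not well above background in a channel.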

Other observations

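The tests of dye effects, of the control line, of gene dosage and of all shifted windows together were chosen after the results were seen, as were the windows and their size limit.

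The 5055 genes called against LACZ came from arrays with no dye swap. Of 1605 called genes with another kept probe, the other probes pointed the same way in 90.0%, against 67.8% for 3887 genes not called, which argues against an effect of dye on single probes as the whole cause. A dye effect on a whole transcript stays open. The covariance of the lines' ratios was 0.29, and with 1 LACZ line a divergence of that line and an effect of SChLAP1 cannot be told apart.

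Of 152 windows of 20 Mb (hg18, at least 30 genes), 7 had a median at least 0.25 from 0 in the same direction in both lines. Lower were the 3 first windows of chromosome 3 (-0.39, -0.38 and -0.39), chromosome 8 from 20000001 to 40000000 (-0.38) and chromosome 18 from 60000001 to 80000000 (-0.45), and higher the first of chromosome 12 (0.30) and chromosome 20 from 20000001 to 40000000 (0.34). Shuffling runs of 10 neighbouring genes gave at most 2 such windows in 1000 shuffles (permutation p = 0.001, the smallest they can give), which argues against chance placement of small gene clusters, and removing a trend with local gene density left 6 of the 7 windows past the limit and the median of 476 genes on chromosome 3 below 80 Mb at -0.34, against -0.37 before. A difference in gene dosage between the LACZ line and both SChLAP1 lines stays open: of 280 genes in that part of chromosome 3 that passed no test, 68.2% lay below 0, but the region was picked for its shift, so this does not decide, no DNA was measured, and a regional effect of SChLAP1 was not tested.

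The isoform lines differed along with local gene density, the number of array genes within 1 Mb. Genes in dense regions were higher in isoform 1 (a Spearman correlation of 0.40 across genes, which are not independent). The correlation was 0.39 on slide 1 and 0.38 on slide 2, a ratio of 0.989, which argues against variation between hybridisations. It was 0.32, 0.43 and 0.42 among genes of low, middle and high signal. A difference in labelling or sample quality between the Cy5 targets may give this, and a difference between the lines was not tested and stays open too.

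In the scanner software's normalized ratios the 10 spike-in probes were higher on the isoform 1 arrays than on the isoform 2 arrays. The difference was 0.75 to 1.11 on the log2 scale and 0.94 on average, on both slides. No explanation was tested.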
